A study of Homo sapiens with 9 samples.

How the data were processed

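Total RNA of MiaPaCa2 cells was labelled and hybridised to Affymetrix arrays, 1 array for each of 9 samples. Per the labels, the cells were grown to 70% confluence, and the labels describe the supernatant both as added a stated time before harvest and as followed by hourly harvests. Groups were taken from the labels: 8 exposed arrays at 1, 2, 3, 4, 5, 6, 7 and 24 h and 1 control at 24 h, whose title also names the treatment of the other arrays.

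The deposited log2 values were made with RMA, which corrects the background, normalizes between arrays and summarises the probes of a probe set, per the submitters' processing notes; its version, the array software and the chip definition are not given in the sources used here. The value table held 54675 probe sets. The authors also deposited a filtered table of 6370 probe sets with the same log2 values, to within 5.00e-09, whose filter rule is not given in the sources used here. Probe sets were named through the platform annotation: 41097 had 1 gene symbol, 1801 several and 11777 none. Of the probe sets with 1 symbol, 41043 were matched by their Entrez ID to a gene table of the assembly GRCh38.p14, used for names and the kind of gene. Probe sets with several symbols or none were left out. Each of 19775 genes was represented by its probe set with the highest mean over the 9 arrays, and the 12402 genes with a mean of at least 5 were kept. Array values carry no read depth, and the number of arrays limits the precision.

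Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over 12402 genes, threshold 0.05). The model held the centred hour, an indicator of the 24 h array and an indicator of the control array. The spread came from the 7 hourly arrays about a line over time, with 5 residual degrees of freedom and 3.72 prior degrees of freedom. The lone 24 h and control arrays were assumed to vary as the hourly arrays did. The contrasts were the slope over 1 to 7 h, the mean of 1 to 7 h minus the control, and 24 h minus the mean of 1 to 7 h. P-values measure the scatter of these arrays, which may be technical. Each exposed array was also set against the control without a test, as a count of genes at least 2-fold apart, and each list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins.

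The comparisons, the tests, the alternative settings, the rule for named genes and 28 gene lists were fixed before the data were examined. Named genes were, for the contrasts with the control and with 24 h, the 10 with the largest positive and the 10 with the largest negative difference among genes that passed. For the slope they were the 12 of each direction that passed, and where none passed the 5 with the smallest p in each direction. For 24 h and 1 h against the control they were the 12 highest and the 12 lowest genes. In a list, up to 4 members with the largest difference were named. Outside this rule ATF3, LDHA, RGS5, IER3, COL1A1, THY1, IRS2, XBP1, IGFBP4, KNL1, SGO1 and, from the fit without the 5 h array, ORC1, POLD3, KLF9, JUNB, ZFP36 and KLF10 were named after their values had been seen. Of the lists, 27 had at least 3 measured genes and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. No list call held with an estimated correlation.

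The alternatives were robust estimation with an intensity trend, array weights, other filters, the mean over probe sets, another quantile normalization, a shift of the arrays to 1 median, the authors' filtered table, other scales of time, no time term, leaving out each hourly array, camera with an estimated correlation, fry, and a 1.5-fold threshold. Protein-coding genes alone and an exact permutation over the orders of the hourly arrays were added after the data had been seen. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables, and matplotlib 3.10.9 drew the figures.

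The test was checked on simulated data with 12402 genes and 100 changed genes for each size. For the slope, 61% of genes changed by 0.1 per h and 94% of those changed by 0.2 per h were recovered, with 15 false calls. For the control contrast, 42% of genes changed by 0.5 and 94% of those changed by 1 were recovered, with 8 false calls. For the 24 h contrast, 60% of genes changed by 0.5 and 94% of those changed by 1 were recovered, with 13 false calls. In these data every array of a gene was drawn with the same spread. The check therefore cannot show how many false calls arise where the lone control or 24 h array varies otherwise. Genes were also drawn independently of each other, and the real 5 h array scattered more than the simulated arrays allowed for (SD 0.165, against 0.079 to 0.102). The shares recovered for the slope are thus not the power of that test in the real data. There a slope of -0.196 per h (TP53INP1) did not pass.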

Results

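Gene expression was measured in MiaPaCa2 cells, an established human pancreatic carcinoma line, that had been given the culture supernatant of pancreatic stellate cells. Stellate cells are the fibroblast-like cells of the pancreas that lay down matrix around tumours, and the labels call the donor cells naive. The series held 9 Affymetrix arrays, of which 8 came from exposed cells harvested after 1, 2, 3, 4, 5, 6, 7 and 24 h and 1 from a control at 24 h. Each of the 9 groups held 1 array, so that no value had replicates and the number of arrays limited the precision. The control array is described as a control in the labels, but its title also carries the treatment named for the other arrays, and what the control cells received is not stated there. The labels leave open whether the cells were harvested together or in turn, so that hours of exposure could not be separated from time in culture, between the hourly arrays or against either 24 h array. Values are log2 expression of 12402 genes, and errors are standard errors (SE) from a fit in which the scatter of the 7 hourly arrays about a line over time stood for the spread between arrays.

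The arrays had closely matching medians, from 4.92 to 4.97 on the log2 scale over all probe sets. The control array and the 5 h array stood apart from the others. Their median correlation with the remaining arrays, across probe sets, was 0.991 for each, against 0.996 or more for the other 7 arrays. The 5 h array had the largest scatter about the lines over time (SD 0.165, against 0.079 to 0.102 for the other hourly arrays). It also had the largest difference between 3' and 5' probe sets of ACTB, at 2.24, where the other 8 arrays lay between 1.58 and 1.98. The array closest to the 24 h array was the 1 h array.

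**Figure D1:**
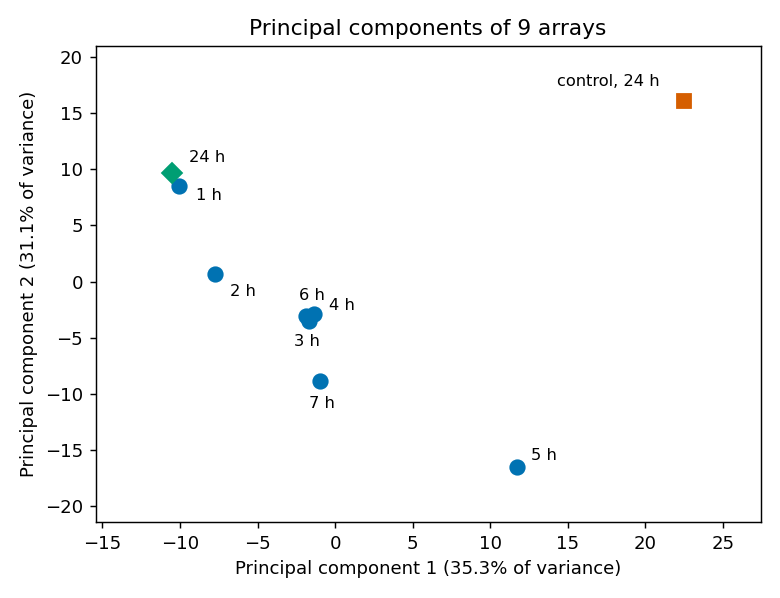
Scores of the 9 arrays on the first principal components of 12402 genes, with component 1 (35.3% of the variance) on the horizontal axis and component 2 (31.1%) on the vertical axis; each point is 1 array, circles mark the 7 hourly arrays, the diamond the 24 h array and the square the control. The control (22.47, 16.12) and the 5 h array (11.70, -16.58) lie away from the rest, and the 24 h array (-10.49, 9.70) lies beside the 1 h array (-10.05, 8.53).

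The first comparison set the 7 hourly exposed arrays against the control, to ask which genes differed in cells that had met the supernatant. MMP1, a collagenase that degrades fibrillar collagen, was higher by 2.73 ± 0.29 (SE; 6.65-fold; adjusted p = 0.00135). LYZ, which encodes lysozyme, was higher by 2.38 ± 0.11 (5.21-fold; adjusted p = 6.31e-05), and SLC7A11, the cystine transporter, by 1.59 ± 0.11 (adjusted p = 0.000275). The metallothionein gene MT1M was lower, by -2.80 ± 0.54 (adjusted p = 0.0129), and KIF20A, a kinesin of cytokinesis, by -1.44 ± 0.10 (adjusted p = 0.000325). All 5 of these genes differed in the stated direction in each of the 8 exposed arrays.

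In limma's test 1721 of 12402 genes passed an adjusted p of 0.05, of which 726 were higher in the exposed arrays and 995 lower. Among them 33 were higher and 45 lower by at least 2-fold. Beyond the genes above, those with the largest positive differences were SCD5, a stearoyl-CoA desaturase (2.77 ± 0.36), APOBEC3G, a cytidine deaminase (1.78 ± 0.29), MAP2, a microtubule-associated protein (1.60 ± 0.16), TRIM4 (1.59 ± 0.28), DHRS2 (1.59 ± 0.11), ID2, an inhibitor of basic helix-loop-helix factors (1.43 ± 0.27), and EMP1, a membrane protein (1.40 ± 0.07). The largest negative differences, besides MT1M and KIF20A, were those of NIBAN1 (-2.24 ± 0.23), CHI3L2 (-2.08 ± 0.26), NAV2 (-1.97 ± 0.19), PARD6G-AS1 (-1.73 ± 0.10), CCDC18 (-1.46 ± 0.13), NEURL1B (-1.45 ± 0.10), LOC100272217 (-1.42 ± 0.09) and LINC01004 (-1.37 ± 0.24). Probe sets of 1 gene did not always move together: over its bright probe sets the difference ran from -0.24 to 2.77 for SCD5, from -0.33 to 1.59 for TRIM4, from 0.03 to 1.78 for APOBEC3G, from 0.26 to 1.75 for EMP1, from -1.97 to -0.03 for NAV2 and from -1.73 to -0.11 for PARD6G-AS1. The test takes the lone control array to vary as the hourly arrays did. The number of genes that passed (control against 1 to 7 h) was 2889 without the 5 h array, 1080 without the 3 h array and 1119 without the 4 h array, and the direction of the majority depended on the scaling: after another quantile normalization 1183 genes were higher and 903 lower, and with the arrays shifted to 1 median 1370 were higher and 820 lower.

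**Figure D2:**
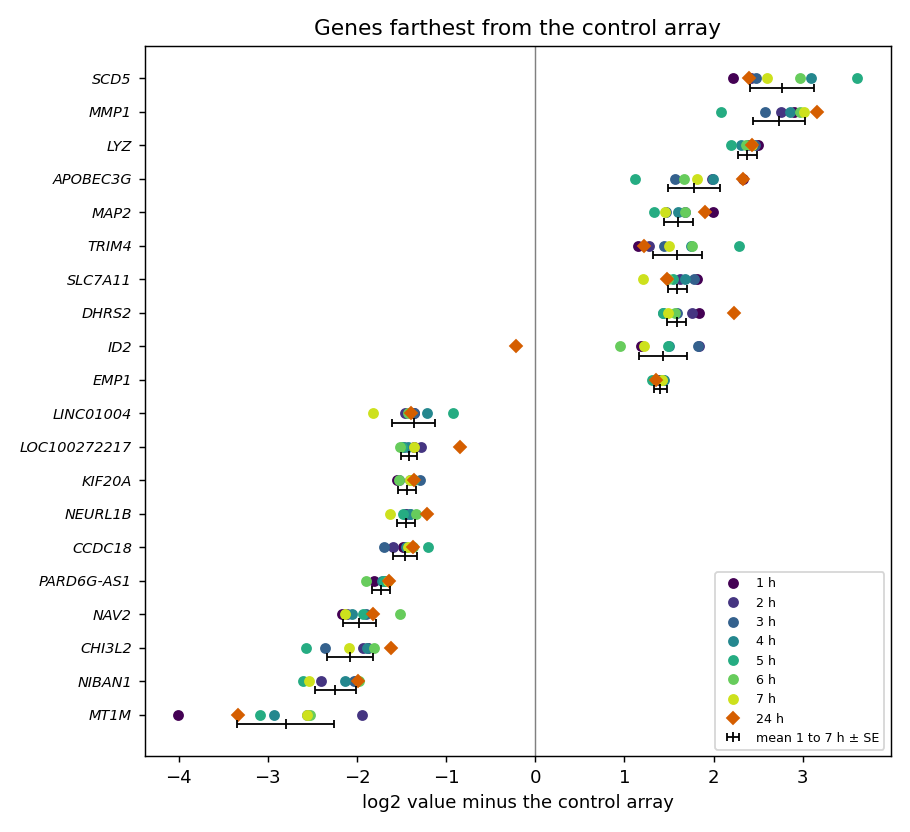
Difference in log2 value from the control array (horizontal axis) for the 10 genes with the largest positive and the 10 with the largest negative difference; circles are the hourly arrays coloured by hour, diamonds the 24 h array, and bars below each row the mean over 1 to 7 h with its SE. Except for ID2 at 24 h (-0.22), each array lies on the same side of the control as the gene's mean.

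The lists of genes fixed by function showed which groups differed together. Of 22 measured G2/M and mitosis genes, 21 were lower in the exposed arrays and passed the test, and all 22 passed when adjusted over the list alone. Examples are CENPE, a kinetochore motor (-1.25 ± 0.14), HMMR (-1.06 ± 0.11) and the mitotic kinase AURKA (2.00-fold lower). The list's median was -0.74 (limma's camera, adjusted p = 5.31e-20; adjusted p = 0.142 with an estimated correlation). Of 11 heat shock genes, 6 passed as lower and 5 did not pass, and adjusted over the list alone 8 passed. Among them were CHORDC1 (-0.95 ± 0.15), HSPA4L (-0.65 ± 0.10) and the co-chaperone DNAJA1 (-0.58 ± 0.08), with a list median of -0.41 (camera adjusted p = 1.48e-05; adjusted p = 0.0817 with an estimated correlation). The 23 genes of G1/S and replication did not differ as a list in the mean over 1 to 7 h (median -0.02, camera adjusted p = 0.774). Of them 0 passed as higher and 2 as lower, CLSPN (-0.40) and TYMS (-0.33), and adjusted over the list alone 0 passed. This mean joins values of opposite sign: the list's median difference from the control was -0.287 at 1 h and 0.107 at 6 h. At 24 h it was -0.368.

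The lists of NRF2 targets, the amino acid and integrated stress response, cholesterol synthesis, fatty acid synthesis and hypoxia passed camera as higher in the exposed arrays, and none did with an estimated correlation. Of 13 targets of NRF2, the regulator of antioxidant genes, 7 passed as higher, 6 did not pass, and adjusted over the list alone 8 passed. They included SLC7A11, the aldo-keto reductase AKR1C1 (1.14 ± 0.12) and the heme oxygenase HMOX1 (0.89 ± 0.14), and the list's median was 0.32 (camera adjusted p = 1.15e-06; adjusted p = 0.0817 with an estimated correlation). SLC7A11 is also a member of the amino acid and integrated stress response list, so these lists are not independent. Of 19 genes of the amino acid and integrated stress response, 11 passed as higher, 1 as lower and 7 did not pass. Adjusted over the list alone 12 passed as higher and 3 as lower. The cystathionine lyase CTH (1.08 ± 0.14), the asparagine synthetase ASNS (0.94 ± 0.11) and the transcription factor ATF4 (0.88 ± 0.07) were higher and ATF3 was lower (-0.68 ± 0.16). The median of this list was 0.34 (camera adjusted p = 5.25e-05; adjusted p = 0.112 with an estimated correlation). Of 15 genes of cholesterol synthesis, 5 passed as higher, among them INSIG1 (0.88 ± 0.12), HMGCS1 (0.70 ± 0.12) and MSMO1 (0.61 ± 0.08). The other 10 did not pass, and adjusted over the list alone 8 passed. Their median was 0.26 (camera adjusted p = 5.81e-06; adjusted p = 0.0817 with an estimated correlation). Of 8 genes of fatty acid synthesis, ME1 (0.80 ± 0.08) and SCD (0.41 ± 0.10) passed as higher. Adjusted over the list alone 4 passed as higher and 1 as lower (median 0.15, camera adjusted p = 0.0439; adjusted p = 0.301 with an estimated correlation), and without the 5 h array the list did not pass (camera adjusted p = 0.0767). Of 18 genes of hypoxia and glycolysis, 3 passed as higher, SLC2A3 (0.64 ± 0.10), BNIP3L (0.63 ± 0.11) and LDHA (0.31 ± 0.09). Adjusted over the list alone 5 passed as higher and 1 as lower (median 0.08, camera adjusted p = 0.0439; adjusted p = 0.464 with an estimated correlation). The hypoxia and fatty acid lists lost their call after another quantile normalization, after the median shift and with no filter, and the hypoxia and amino acid lists in the authors' filtered table. The hypoxia list also lost its call with fry.

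Camera also passed the TGF-beta response, invasion and protease, YAP and TEAD, immediate early and MAPK feedback lists as higher, and again none with an estimated correlation. Of 17 genes of the TGF-beta response, 10 passed as higher, 1 as lower and 6 did not pass. Adjusted over the list alone 11 passed as higher and 1 as lower. ID2, the transcription factor SNAI2 (1.33 ± 0.26) and the receptor-like BAMBI (1.05 ± 0.21) were higher, and TGFB1, the ligand itself, was lower (-0.92 ± 0.21). The list's median was 0.53 (camera adjusted p = 1.48e-05; adjusted p = 0.0985 with an estimated correlation). Of 14 invasion and protease genes, 6 passed as higher and 8 did not pass, and adjusted over the list alone 6 passed. Besides MMP1 they included ADAM9 (0.66 ± 0.08) and TIMP3, a protease inhibitor (0.47 ± 0.12). The median of that list was 0.25 (camera adjusted p = 5.25e-05; adjusted p = 0.169 with an estimated correlation). Of 10 targets of YAP and TEAD, CCN1 (1.17 ± 0.13), NT5E (0.77 ± 0.10) and AXL (0.66 ± 0.07) passed as higher. Adjusted over the list alone 4 passed (median 0.26, camera adjusted p = 0.0151; adjusted p = 0.239 with an estimated correlation). Of 22 immediate early genes, 4 passed as higher and 1 as lower, and adjusted over the list alone 5 and 2. CCN1, KLF4 (0.47 ± 0.07) and IER3 (0.44 ± 0.11) were among the higher ones (median 0.20, camera adjusted p = 0.00657; adjusted p = 0.434 with an estimated correlation). Of 18 MAPK feedback genes, 2 passed as higher, ETV1 (0.79 ± 0.11) and the cyclin CCND1 (0.57 ± 0.11), and 1 as lower. Adjusted over the list alone 4 passed as higher and 1 as lower (median 0.13, camera adjusted p = 0.0275; adjusted p = 0.464 with an estimated correlation). For the immediate early and MAPK feedback lists the mean over 1 to 7 h joins unlike hours. The immediate early median difference from the control was 0.419 at 1 h and 0.006 at 7 h. For MAPK feedback genes it was 0.251 at 1 h, -0.017 at 7 h and 0.284 at 24 h. The MAPK feedback list lost its call after another quantile normalization and with fry, and with no time term the MAPK feedback, immediate early, hypoxia and endothelial lists lost theirs.

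Of the markers of other cell types, 3 lists passed camera as higher, and none with an estimated correlation. Of 10 stellate cell and fibroblast markers, 4 passed as higher in the exposed arrays and 6 did not pass, and adjusted over the list alone 5 passed. The collagen genes COL6A3 (0.94 ± 0.09), COL3A1 (0.94 ± 0.11) and COL1A2 (0.67 ± 0.13) and the pericyte gene RGS5 (0.34 ± 0.07) were higher, while COL1A1 (7.42 in the mean of the hourly arrays and 7.33 in the control) and THY1 (5.66 and 5.61) did not pass. The list's median was 0.26 (camera adjusted p = 0.00215; adjusted p = 0.169 with an estimated correlation). The list did not pass in the mean over probe sets (median 0.06; stellate cell and fibroblast markers: control against 1 to 7 h). In the authors' filtered table, which holds another probe set of COL1A2, the median was -0.76 and the difference of COL1A2 was -0.20 (COL1A2: control against 1 to 7 h). The 3 measured leukocyte markers had a median of 0.48, with LYZ passed and CD14 and CD74 not passed, also when adjusted over the list alone (camera adjusted p = 0.0151; adjusted p = 0.152 with an estimated correlation). The 3 measured endothelial markers had a median of 0.39, with TEK and EMCN passed, also when adjusted over the list alone (camera adjusted p = 0.0455; adjusted p = 0.198 with an estimated correlation), and without the 5 h array the list did not pass (camera adjusted p = 0.0860), nor after another quantile normalization, after the median shift or with no filter.

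The second comparison set each exposed array against the control array alone, to follow the course of the difference; with 1 array on each side it has no replicate check and no test. At 24 h, the time shared with the control, MMP1 was 3.16 above the control (8.94-fold), LYZ 2.43 and SCD5 2.40. APOBEC3G (2.33), DHRS2 (2.23), PRND (1.97), MAP2 (1.90), the endothelial receptor gene ROBO4 (1.61), RBM47 (1.52), LEMD1 (2.84-fold), SLC7A11 (1.48) and KLF9 (1.46) completed the 12 highest. The 12 lowest were MT1M (-3.34), NIBAN1 (-1.99), the mitochondrially encoded ND6 (-1.84), NAV2 (-1.82), FTX (-1.70), LOC100190986 (-1.67), RPS16P5 (-1.64), PARD6G-AS1 (-1.64), CHI3L2 (-1.62), SMG1P5 (-1.60), GTF2H2B (-1.56) and HINT3 (-1.54). Probe sets differed here too: in the mean over 1 to 7 h, the difference from the control ran from 0.15 to 1.31 for ROBO4. The range was 0.22 to 1.01 for RBM47, 0.42 to 0.95 for PRND and -1.50 to -0.50 for HINT3. At 24 h 58 genes were at least 2-fold above the control and 86 at least 2-fold below it.

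The differences were already of similar size at 1 h, when 51 genes were at least 2-fold above the control and 89 below it. MMP1 was then 2.90 above the control, LYZ 2.50, APOBEC3G 2.33, SCD5 2.22, MAP2 1.99, DHRS2 1.84, SLC7A11 1.82 and ROBO4 1.48. FOS, an immediate early transcription factor, was 2.44 above the control at 1 h (5.43-fold), 1.56 at 2 h and -0.15 at 24 h. The MAPK phosphatase DUSP6 (1.59), the p53-induced TP53INP1 (1.47) and KLF9 (1.73) were also among the 12 highest at 1 h. The 12 lowest at 1 h were MT1M (16.0-fold lower), NAV2 (-2.16), NIBAN1 (-2.01), CHI3L2 (-1.88), HINT3 (-1.88), LOC100190986 (-1.87), FTX (-1.85), PARD6G-AS1 (-1.80), GTF2H2B (-1.79), ZNF431 (-1.64), ND6 (-1.60) and ANKRD36B (-1.56). From 2 to 7 h the counts above and below the control were 51 and 90 at 2 h, 34 and 60 at 3 h, 41 and 58 at 4 h, 39 and 97 at 5 h, 40 and 89 at 6 h, and 37 and 109 at 7 h. Shifting the arrays to 1 median moved the split above and below to 39 and 43 (3 h against control), 46 and 45 (4 h against control), 49 and 42 (5 h against control) and 46 and 63 (7 h against control). Another quantile normalization moved it to 40 and 43 at 3 h, 48 and 43 at 4 h and 41 and 74 at 7 h.

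In all 8 exposed arrays 12 genes were at least 2-fold above the control, among them EMP1, IGFBP4, MMP1 and SLC7A11, and 17 at least 2-fold below it, among them CENPE, KIF20A, KNL1 and SGO1. The 8 comparisons share the control array. Unchanged arrays, the control included, were simulated 100 times with the spread of the hourly arrays. The median number of genes 2-fold apart in all 8 was then 0 in either direction and the highest was 1. A control array off in quality, culture or day was not simulated, and it would put the same genes apart in all 8 comparisons. Part of the overlap may still come from the shared control. Against 10000 random lists matched on mean expression, the median of the G2/M and mitosis genes lay at percentile 0 at 24 h (-0.84), 1 h (-0.91) and 7 h (-0.74). The median of the G1/S and replication genes was -0.37 at 24 h and -0.29 at 1 h, both at percentile 0, and 0.07 at 7 h, at percentile 95.3. Immediate early genes had a median of 0.42 at 1 h (percentile 100) and 0.04 at 24 h (percentile 67.8). Interferon response genes had a median of 0.40 at 1 h and 0.29 at 24 h, both at percentile 100, but of 0.02 at 5 h (percentile 87.2). Such random lists take no account of correlation within a list, estimated at 0.49 for the interferon response genes.

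The third comparison followed the 7 hourly arrays, to ask which genes changed during the exposure itself. In limma 0 of 12402 genes passed an adjusted p of 0.05 (smallest adjusted p = 0.0731). With array weights 5 genes passed (trend over 1 to 7 h), with robust estimation and an intensity trend 25, and against the log2 of the hour 74. At an unadjusted p under 0.05 there were 1944 genes, 606 with a positive and 1338 with a negative slope, where 620 would come by chance on average. Genes vary together, so the number under chance spreads widely. Of 100 drawn orders of the hourly arrays, the real one included, 3 gave as many, and the highest was 2436. The genes with the smallest p among positive slopes, which did not pass, were the exonuclease EXO1 (0.13 ± 0.02 log2 per h), the replication factor MCM10 (0.14 ± 0.02), PSMC3IP (0.11 ± 0.02), LRR1 (0.10 ± 0.02) and the recombination helicase RAD54B (0.08 ± 0.01). Among negative slopes they were the clock-associated repressor BHLHE40 (-0.18 ± 0.02), TP53INP1 (-0.20 ± 0.02), KIZ (-0.12 ± 0.02), PACSIN1 (-0.12 ± 0.02) and CREBRF (-0.21 ± 0.03), which did not pass either. Without the 5 h array 73 genes passed, 9 with a positive slope, including EXO1, MCM10, ORC1 and POLD3, and 64 with a negative slope, including KLF9 (-0.26 ± 0.03), JUNB (-0.19 ± 0.02), ZFP36 (-0.15 ± 0.02) and KLF10 (-0.13 ± 0.02). The genes named from this fit without the 5 h array, other than EXO1 and MCM10, were chosen after their values had been seen.

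In camera 5 lists passed with a positive slope, and none with an estimated correlation. All 23 measured G1/S and replication genes had a positive slope, led by MCM10, the cyclin CCNE2 (0.10 ± 0.02), the licensing factor CDC6 (0.10 ± 0.02) and E2F1 (0.09 ± 0.02). None of them passed over all genes and 18 passed when adjusted over the list alone; the median slope was 0.06 log2 per h (camera adjusted p = 4.02e-18; adjusted p = 0.290 with an estimated correlation). Of 17 MYC and ribosome biogenesis genes, 16 had a positive slope, with RRS1 (0.07 ± 0.02) and NOP2 (0.07 ± 0.01) as examples. Over all genes 0 passed, and 3 when adjusted over the list alone (camera adjusted p = 9.63e-07; adjusted p = 0.105 with an estimated correlation). Of 15 genes of cholesterol synthesis 13 had a positive slope, with 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.000149; adjusted p = 0.204 with an estimated correlation). Of 22 G2/M and mitosis genes 20 had a positive slope, with 0 passed by either adjustment (camera adjusted p = 0.00063; adjusted p = 0.783 with an estimated correlation). Of 11 heat shock genes 8 had a positive slope, with 0 passed over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.299 with an estimated correlation).

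Another 5 lists passed camera with a negative slope, and none with an estimated correlation. Of 22 immediate early genes, 17 had a negative slope, led by FOS (-0.26 ± 0.08), EGR1 (-0.22 ± 0.07), JUNB (-0.21 ± 0.04) and EGR3 (-0.18 ± 0.04). Over all genes 0 passed, and adjusted over the list alone 13 passed with a negative and 1 with a positive slope (camera adjusted p = 2.84e-05; adjusted p = 0.446 with an estimated correlation). Of 15 FOXO and quiescence genes, 13 had a negative slope, led by KLF9 (-0.29 ± 0.05), TP53INP1, the cyclin CCNG2 (-0.19 ± 0.03) and TXNIP (-0.16 ± 0.05). Over all genes 0 passed, and 9 adjusted over the list alone (camera adjusted p = 4.25e-06; adjusted p = 0.471 with an estimated correlation). Of 18 MAPK feedback genes 16 had a negative slope, with DUSP6 (-0.17 ± 0.04) and ETV1 (-0.15 ± 0.02) as examples, and 7 passed when adjusted over the list alone (camera adjusted p = 0.00063; adjusted p = 0.471 with an estimated correlation). Among 12 circadian clock genes 10 slopes were negative and 2 genes passed when adjusted over the list alone (camera adjusted p = 0.0340; adjusted p = 0.647 with an estimated correlation). Among 12 p53 targets 10 slopes were negative and 1 gene passed when adjusted over the list alone (camera adjusted p = 0.0340; adjusted p = 0.783 with an estimated correlation). In an exact permutation over the 5040 orders of the hourly arrays, two-sided and adjusted over 27 lists, the mean slope passed for the G1/S, MYC and ribosome, cholesterol and immediate early lists (adjusted p = 0.0321 each) and for the heat shock genes (adjusted p = 0.0471), but not for FOXO and quiescence (adjusted p = 0.0857), MAPK feedback (0.0934), circadian clock (0.117), p53 (0.141) or G2/M genes (0.476). Without the 5 h array it also passed for the FOXO and quiescence, MAPK feedback, circadian clock, IL-6 and STAT3, amino acid and invasion lists (adjusted p = 0.0375 each) and for p53 targets (0.0409). In camera the slopes of the IL-6 and STAT3, amino acid and invasion lists did not pass without the 5 h array (adjusted p = 0.1323, 0.1827 and 0.4225). They did not pass camera with all arrays either.

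**Figure D3:**
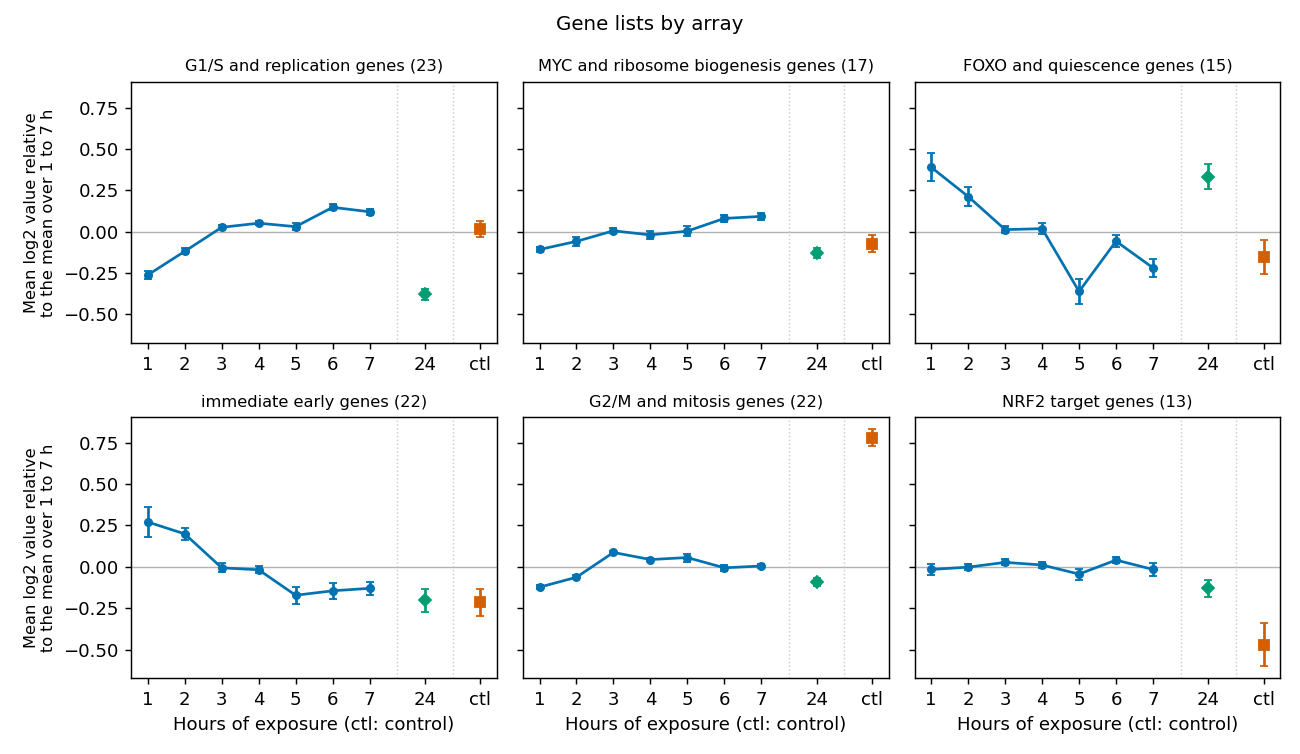
Mean log2 value of 6 gene lists in each array relative to the gene's mean over the 7 hourly arrays (vertical axis) against hours of exposure (horizontal axis, with the 24 h array and the control, ctl, set apart and not to scale); bars are the SEM over the genes of the list, whose number stands in brackets, and show the spread between genes, not between arrays. The G1/S and replication genes go from -0.26 at 1 h to 0.12 at 7 h and lie at -0.38 at 24 h, and the G2/M and mitosis genes lie at 0.78 in the control.

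The fourth comparison set the 24 h array against the hourly arrays, to ask what differed late in the exposure. RHOU was higher at 24 h by 0.77 ± 0.08 (adjusted p = 0.0427) and was the 1 gene of 12402 that passed in limma. It was 0.01 above the control at 24 h and from -0.85 to -0.70 relative to it at 1 to 7 h. At an unadjusted p under 0.05 there were 1946 genes, 1214 higher and 732 lower at 24 h, and without the 5 h array 9 genes passed. RHOU itself did not pass with the 2, 3, 4, 6 or 7 h array left out, and its difference was 0.30 in the mean over its probe sets (RHOU: 24 h against 1 to 7 h), which did not pass.

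In camera 5 lists passed as lower and 1 as higher at 24 h, and none with an estimated correlation. With fry only the G1/S and replication list and the MYC and ribosome biogenesis list among them passed. All 23 G1/S and replication genes were lower at 24 h than in the mean of the hourly arrays, led by MCM10 (-0.73 ± 0.10), CCNE2 (-0.71 ± 0.14), the ribonucleotide reductase subunit RRM2 (-0.63 ± 0.11) and CDC6 (-0.55 ± 0.10). Over all genes 0 of them passed and 19 passed when adjusted over the list alone; the median was -0.34 (camera adjusted p = 2.00e-20; adjusted p = 0.353 with an estimated correlation). Of 17 MYC and ribosome biogenesis genes 15 were lower, with NIP7 (-0.37 ± 0.08) and ODC1 (-0.33 ± 0.07) as examples, 0 passed over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0003; adjusted p = 0.282 with an estimated correlation). Of 22 immediate early genes 17 were lower, led by FOS (-1.14 ± 0.46) and EGR1 (-0.88 ± 0.37), with 2 passed when adjusted over the list alone (camera adjusted p = 0.00175; adjusted p = 0.640 with an estimated correlation). Of 22 G2/M and mitosis genes 18 were lower, with 0 passed by either adjustment (camera adjusted p = 0.00569; adjusted p = 0.871 with an estimated correlation). Of 13 NRF2 targets 9 were lower, led by AKR1C1 (-0.54 ± 0.12), which passed when adjusted over the list alone (camera adjusted p = 0.00606; adjusted p = 0.508 with an estimated correlation). Of 15 FOXO and quiescence genes 13 were higher at 24 h, led by CCNG2 (0.91 ± 0.19), KLF9 (0.84 ± 0.30) and BCL6 (0.59 ± 0.12), with 2 passed when adjusted over the list alone (camera adjusted p = 0.00175; adjusted p = 0.681 with an estimated correlation). The test takes the lone 24 h array to vary as the hourly arrays did. The mean of 1 to 7 h also joins unlike hours. As list means relative to it, G2/M genes lay at -0.09 at 24 h and -0.123 at 1 h, and FOXO genes at 0.334 and 0.39. Immediate early genes lay at -0.203 at 24 h, near the -0.172 at 5 h, with 0.271 at 1 h. These 24 h values were thus near single hourly ones. The G1/S list, at -0.379, lay below its lowest hourly value (-0.261). So did the MYC (-0.129, against -0.107) and NRF2 lists (-0.131, against -0.044).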

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

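The tests of the control array and of the 5 h array (except the exchange of the control with other arrays), the shares of orders without the 1 h or the 5 h array and the list slopes under permuted orders were chosen after the result had been seen.

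The control array stood apart from the 7 hourly arrays, with 1721 genes past the threshold. A response that built up over the hours is argued against, as the main source of the difference, by the 1 h array. Over these genes the median ratio of the 1 h difference to the mean 5 to 7 h difference was 0.972, although 8.5% of them had a ratio under 0.5. The 1 h array also helped to choose these genes, and an offset of the control array would bring the ratio near 1. A smaller response that built up on top of such an offset is not excluded. Degraded control RNA stays open: its difference between 3' and 5' probe sets of ACTB, 1.858, lay inside the 1.585 to 1.975 of the exposed arrays other than 5 h, but that of GAPDH, 0.154, lay above their 0.099 to 0.148. Extra unspliced or intergenic RNA on the control array stays open. Of the called genes, 267 were higher in the exposed arrays by 0.5 or more, 245 also with the trend over brightness taken off. A shift shared by genes of like brightness leaves these 245. They cannot decide the question, since they are part of the calls to be explained and the bound was set after these were seen. For genes higher in the control, the share of noncoding symbols was 0.771 times that of tested genes, while the Alu signal was highest in the control (14.373, against 13.906 to 14.29). That share covers all called genes higher in the control. The genes with the largest differences, which include the noncoding PARD6G-AS1 and LINC01004, were not counted apart, so the share does not speak for them. With each of 8 other arrays in the control's place the highest count was 7, where the moved control widened the spread, and 1 of 9 arrangements, the real one, gave 1721, too few for a share under 0.05; with the other left out, the 5 h array gave 1362 and the control 2889, and a difference in culture or array day and an effect of the supernatant present from 1 h both stay open and untested.

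The 5 h array stood apart from the other hourly arrays, and it was picked out by signals outside the gene comparisons, above the control: the difference between 3' and 5' probe sets was 2.236 for ACTB (control 1.858) and 0.195 for GAPDH (control 0.154). The Alu signal went the other way, at 14.29 in the 5 h array and 14.373 in the control. An exchange of the 5 h and control labels stays open: the median position of the 5 h array was 0.88 on a scale from the control at 0 to the other hourly arrays at 1, but with these 2 arrays in each other's place it was 0.823, so that the measure cannot separate the cases. Degradation of the 5 h RNA may contribute, since 2.236 lies above the 1.585 to 1.975 of the 6 other hourly arrays. Extra unspliced or intergenic RNA may contribute too, since noncoding symbols deviated by 0.054 more than protein-coding ones, against -0.041 to 0.015 in the other hourly arrays, and a biological change at 5 h alone stays open and untested.

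Slopes over 1 to 7 h were turned back at 24 h: across 12402 genes, which are not independent replicates, the slope and the 24 h difference had a correlation of -0.508. The 1 h array alone and the 5 h array alone stay open, with correlations of -0.348 and -0.422 without them: a share of 0.146 and 0.0514 of the orders of the remaining arrays gave values as far below 0, which the bound written beforehand had not allowed for. A chance order of the hourly arrays may give the pattern, since a share of 0.0528 of the 5040 orders gave a correlation as far below 0. A passing response to the handling or to the supernatant stays open and was not tested.

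The following results between time points passed limma, for RHOU, or camera with a preset correlation, for the lists. No list held with an estimated correlation (adjusted p from 0.105 to 0.871), and the slopes of FOXO and quiescence, MAPK feedback, circadian clock, p53 and G2/M genes did not pass the permutation of orders (0.0857, 0.0934, 0.117, 0.141 and 0.476). Without the 5 h array the first 4 of these passed it (0.0375 each, and 0.0409 for p53) and G2/M did not. RHOU was 0.773 higher at 24 h than at 1 to 7 h. List medians at 24 h minus 1 to 7 h were -0.341 for G1/S and replication, -0.106 for MYC and ribosome biogenesis, -0.075 for G2/M and mitosis, -0.092 for immediate early, -0.11 for NRF2 target and 0.258 for FOXO and quiescence genes. Median slopes per h were 0.056 for G1/S and replication, 0.03 for MYC and ribosome biogenesis, 0.026 for cholesterol synthesis, 0.017 for G2/M and mitosis and 0.016 for heat shock genes. Median slopes were -0.074 for FOXO and quiescence, -0.062 for immediate early, -0.038 for MAPK feedback, -0.036 for circadian clock and -0.032 for p53 target genes. The number of genes with a slope at an unadjusted p under 0.05 was 1944, against at most 2436 in the other orders of the hourly arrays, and 3 of 100 drawn orders, the real one included, gave as many; this share is under 0.05 for the orders drawn, and the remaining orders were not run. With groups of 1 array, no array could be tested against others of its group.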

How the results depend on the processing

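Protein-coding genes alone and the orders of the hourly arrays were chosen after the data had been seen. No paired analysis was possible because each group held 1 array. Leaving out 1 hourly array gave 0 to 73 genes (trend over 1 to 7 h), 1080 to 2889 (control against 1 to 7 h) and 0 to 9 (24 h against 1 to 7 h), and 8 to 10, 13 to 17 and 6 to 7 lists. The 73 and the 2889 came without the 5 h array. Genes with a slope numbered 25 with robust estimation, 5 with array weights, 21 with the filter at 6.5, 4 after the median shift and 74 against the log2 of the hour. With a square term added, 2 genes passed a joint test of line and square. That test also takes in curved change, so its count is not one of slopes. Genes at 24 h against 1 to 7 h numbered 11 with robust estimation, 2 after the median shift, and 0 with no filter, with the filter at 6.5, in the mean over probe sets and in the authors' filtered table. That table gave 151 genes for the control, where fewer genes were tested. The cause was not tested for the others.

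Lists that passed numbered 4 for the slope and 8 for the control in the authors' filtered table, 2 for the slope on the log2 of the hour to 24 h, and 0 in each contrast with an estimated correlation. With fry 5 passed for the slope, all of which had passed camera, and 3 passed for 24 h. Of these 3, the mesenchymal list had not passed camera at 24 h. The immediate early, NRF2 target, G2/M and mitosis and FOXO and quiescence lists lost their 24 h call with fry. Over all orders of the hourly arrays 5 passed for the slope. Genes at least 2-fold from the control at 1 to 7 h numbered 93, 92, 58, 61, 73, 79 and 92 with the filter at 6.5. In the mean over probe sets they numbered 91, 77, 57, 58, 71, 71 and 66, and 91 at 24 h. At 1.5-fold they numbered 796 (1 h against control), 784 (2 h against control), 634 (3 h against control), 621 (4 h against control), 848 (5 h against control), 660 (6 h against control), 847 (7 h against control) and 816 (24 h against control).

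In the authors' filtered table the sign turned for IDI1 (IDI1: trend over 1 to 7 h, -0.002), COL1A2 (COL1A2: control against 1 to 7 h, -0.197) and the stellate list (stellate cell and fibroblast markers: control against 1 to 7 h, -0.759); the table holds another probe set of COL1A2. With the 24 h array included in the slope by construction, it turned for BAG3 (-0.01), CCNE2 (-0.027), CDC6 (-0.009), CCNA2 (-0.007) and the list of G1/S and replication genes (-0.007). Over all other alternatives and tested results, 1588 values kept their direction and side of the threshold, 105 lost their call and 66 gained one. The 1588 include results that had not passed and still did not. Among them were 486 slopes of single genes, of which 0 had passed, and 206 single-gene values at 24 h, where RHOU alone had passed. Of leave-one-out values 1153 kept both, 35 lost their call and 23 gained one. The 1153 likewise include 309 such slopes and 170 such values at 24 h.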

Other observations

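The list comparisons were fixed with the others, except for the adjustment over a list alone, and IRS2 and XBP1 were named only after their values had been seen.

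Lists that did not pass against the control included single genes that did. Of 16 interferon response genes, 5 passed as higher in the exposed arrays and 1 as lower, and adjusted over the list alone 8 and 3. The ubiquitin ligase gene HERC5 was 2.29-fold higher and ISG15, a ubiquitin-like modifier, was higher by 0.67, while OAS3, an antiviral synthetase, was lower, at -0.90 ± 0.07. Their median was 0.25 (camera adjusted p = 0.0549; adjusted p = 0.609 with an estimated correlation), and without the 5 h array the list passed (camera adjusted p = 0.0107; adjusted p = 0.308 with an estimated correlation). Of 15 FOXO and quiescence genes, 3 passed as higher, TP53INP1 (0.85), YPEL5 (0.62) and IRS2 (0.56), also adjusted over the list alone (median 0.06, camera adjusted p = 0.0606), and without the 5 h array this list passed with a median of 0.12 (camera adjusted p = 0.0231; adjusted p = 0.432 with an estimated correlation). Of 12 IL-6 and STAT3 response genes, the kinase gene PIM1 (0.54) and CISH (0.33) passed as higher, and 3 adjusted over the list alone (median 0.13, camera adjusted p = 0.158). Of 15 endoplasmic reticulum chaperone genes, HSPA5 (0.40), HERPUD1 (0.37) and XBP1 (0.32) passed as higher and CRELD2 (-0.47) as lower, and adjusted over the list alone 4 and 1 (median 0.02, camera adjusted p = 0.510).

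Of 12 p53 target genes, TP53INP1 and ZMAT3 (0.64) passed as higher, also adjusted over the list alone (median 0.02, camera adjusted p = 0.479). Of 11 mesenchymal genes, SNAI2 and TGFBI passed as higher and ZEB1 (-0.35) as lower, also adjusted over the list alone; their median was -0.003 and their mean 0.17 (camera adjusted p = 0.355). Among 10 epithelial genes the cadherin gene CDH3 (0.38) passed (median 0.13, camera adjusted p = 0.0618), among 17 MYC and ribosome biogenesis genes PNO1 (0.83; median 0.03, camera adjusted p = 0.246) and among 12 circadian clock genes BHLHE40 (0.53; median -0.009, camera adjusted p = 0.774), each also adjusted over the list alone. In limma 0 of 16 NF-kB inflammatory genes (median 0.07, camera adjusted p = 0.193) and 0 of 11 housekeeping genes (median 0.04, camera adjusted p = 0.372) passed, and 0 of either adjusted over the list alone. Without the 5 h array 3 NF-kB genes passed as higher and 1 as lower, and 1 housekeeping gene as lower. Of the pancreatic acinar and islet markers CELA3A was measured, with a difference of 0.13, and the list was not tested.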
